A study of Homo sapiens with 6 samples.

How the data were processed

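RNA sequencing of MCF-7 cells was deposited as 6 processed libraries, 3 of cells given the empty pcDNA3.1 vector (Control) and 3 of cells given pcDNA3.1 carrying NFIC1 (NFIC1), harvested 48 h after transfection. Per the labels' protocols, total RNA was taken with Trizol and made into libraries with a directional NEBNext kit. The deposited values are FPKM, fragment numbers scaled to gene length and library total by the authors, per the file headers, with 1 library per file. The aligner, the counting tool, the genome build, the annotation and whether counting used strand are not given in the sources used here. DESeq 1.10.1 is named in the submitters' processing notes, with no role. FPKM divide by gene length and by library total, so a level in 1 gene affects the others only through that total. NFIC made up 0.437% to 0.539% of the FPKM sum in the NFIC1 libraries. Its share of the fragments also depends on gene length and is unknown, so the effect of NFIC on the library total is not bounded by this. The rescaling without NFIC described below uses the FPKM sum as well.

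Depth is unknown. Low values were searched for the steps that whole reads would leave. Among rows under 0.1 FPKM in 2 libraries, no more than 1.99% of the ratios between the libraries fell within any window 1% wide, so relative depth could not be read from them. No interval from counting error is given for that reason. Rows listed at 0 in 1 library or more and at 5 FPKM or more in another numbered 9, and a value of 0 may be a failed estimate rather than an absence of reads. No pair of libraries had more than 0.0158% of tested rows with identical values, so the 6 were treated as separate.

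Symbols were taken from a table of gene names for 19883 of the 19974 Ensembl IDs, and the position of NFIC from GENCODE 29 on GRCh38. The IDs were 99.7% protein-coding genes in that annotation. The 6940 loci named newGene have no symbol and were counted but not named.

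The design fixed before the data were examined named a count model, with limma as the test should the files hold FPKM. Since they hold FPKM, values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, for rows at 1 FPKM or more in 3 libraries or more, and group as the only term. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Benjamini-Hochberg adjusted p under 0.05, two-sided, with no fold minimum, counted as changed, and "rose" and "fell" are used for genes that passed. Of 29 gene lists fixed at the same time, the 22 with 5 or more tested members were tested with camera, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the 22. Camera with an estimated correlation and fry were alternatives. Unlike camera, fry does not compare a list with the other genes. Most of the 22 lists passed under fry, so such a pass says little about a list in particular. Of the 14 lists called with the preset correlation, 4 were called with an estimated one. The estimate was below the preset for p53 targets (-0.0155) and heat shock genes (-0.0238), which lost their calls all the same. The settings therefore differ in more than the correlation, and a lost call does not show that the members of a list are correlated.

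Genes were named by a rule fixed before the data were examined. It takes the NFI family, the 8 largest rises and the 8 largest falls among changed genes with a symbol, a mean of at least 1 FPKM and no overlap between groups, up to 4 members of smallest adjusted p in each list tied to the title (if none passes, the 2 of highest expression), up to 2 in each other list that camera called or that had 3 or more members past the threshold, and STAT1, STAT2, IRF9, JAK1, JAK2, TYK2 and IFNB1 whatever their p. Any other gene named was chosen after its values were seen.

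The fit was tested on simulated data for the comparison of NFIC1 with Control, with 12685 genes of which 200 changed. It recovered 86% of genes changed by 0.5 and 98% of those changed by 1 on the log2 scale, 5.64% of its 195 calls were false, and 0 of them had the wrong sign. The 1 list that was shifted was called, and 0 of the others were. Noise was simulated independently for each gene, so this cannot show how camera behaves where genes are correlated. Of the 979 rows called in the real data, 169 reached 0.5 on the log2 scale, and recovery of smaller changes was not simulated.

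Alternatives were 3 rescalings of the FPKM (median of ratios, upper quartile, and totals without NFIC), a pseudocount of 0.1, no filter and a filter at 0.1 FPKM, fold minimums, replicate number as a term, other variance priors, Ensembl genes only, and leaving out each library in turn. Tests that need counts were not run.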

Results

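RNA was measured by sequencing in MCF-7 cells, an established estrogen receptor-positive line of human breast cancer cells, 48 h after transient transfection by lipofection. Control cells (3 libraries) received the empty pcDNA3.1 expression vector, and NFIC1 cells (3 libraries) received the same vector carrying NFIC1, a form of the transcription factor nuclear factor I C. The files give 1 FPKM value per gene and library for 26914 rows, of which 19974 were Ensembl gene IDs and 6940 were loci named newGene. FPKM sums lay between 426077 and 443002 per library, and read depth is unknown. On the log2 scale the correlation between libraries, computed across genes, was 0.9939 to 0.9953 within groups and 0.9887 to 0.9907 between groups. The first principal component, with 47.2% of the variance, put the 3 Control libraries on one side and the 3 NFIC1 libraries on the other. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical only.

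The first comparison checks the transfected gene. NFIC (ENSG00000141905), a protein-coding gene on chromosome 19 from 3314403 to 3469217 on the forward strand of GRCh38 in GENCODE 29, was listed at 39.4, 24.5 and 18.3 FPKM in the Control libraries and at 1898, 2173 and 2388 FPKM in the NFIC1 libraries. The group means were 27.4 ± 10.9 and 2153 ± 245 FPKM (SD, n = 3 each), a log2 fold change of 6.31 with SE 0.22 and a limma adjusted p of 2.58e-06. A value per gene does not separate vector transcripts from those of the chromosomal gene. The related family members NFIA, NFIB and NFIX had log2 fold changes of -0.03, -0.08 and 0.01, none of which passed the test (adjusted p = 0.894, 0.561 and 0.982).

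The comparison of all genes asks which transcripts differ when NFIC1 is supplied. Of 12685 rows tested, 979 changed, 649 of them higher and 330 lower in NFIC1. These held 942 Ensembl genes, of which 633 were higher and 309 lower. Besides NFIC, the largest rises by the naming rule were in BEST1, a chloride channel (2.92, SE 0.27), SLURP1, a secreted protein of epithelia (2.57, SE 0.10), AKR1B10, an aldo-keto reductase (2.10, SE 0.09), the read-through gene PPAN-P2RY11 (2.09, SE 0.25), the interferon-inducible IFI27 (1.99, SE 0.09) and the chemokine CCL5 (1.74, SE 0.08), all as log2 fold changes, and in complement factor B, CFB, which went from 1.21 ± 0.0311 to 7.88 ± 0.576 FPKM (SD, n = 3 each). The largest falls were in FOSB (-1.73, SE 0.07), SCHIP1 (-1.61, SE 0.16), FOS (-1.11, SE 0.04), NR4A1 (-1.06, SE 0.07), EGR1 (-0.90, SE 0.05), the histone gene H2AC13 (-0.78, SE 0.14), GCHFR, the feedback regulator of GTP cyclohydrolase (-0.76, SE 0.09), and the small GTPase gene RHOB (-0.69, SE 0.05). The limma adjusted p of these 16 genes ranged from 2.58e-06 to 0.0132.

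**Figure D1:**
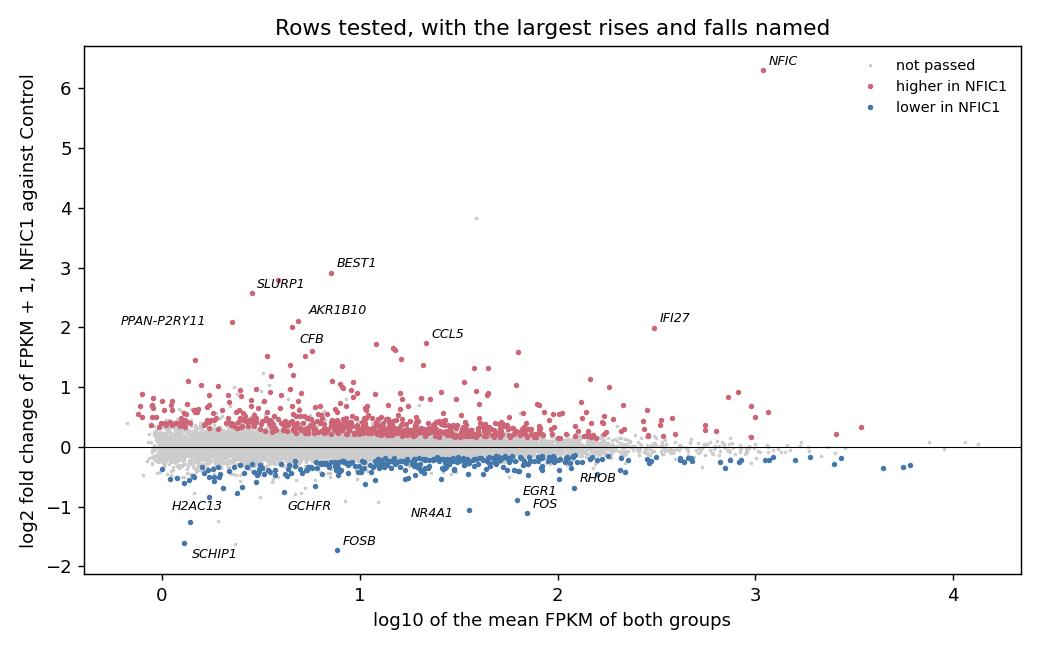
Each point is 1 of the 12685 rows tested, with the log10 of its mean FPKM over both groups on the x axis and its log2 fold change of FPKM + 1, NFIC1 against Control, on the y axis, coloured where the adjusted p was under 0.05. Named genes are the 8 largest rises and the 8 largest falls, and NFIC stands apart at 6.31.

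Most changes were small, since 35 of the 649 rises and 5 of the 330 falls reached 1 on the log2 scale. The groups did not overlap in 29.3% of rows tested, against 10% by chance for 3 libraries against 3. The share of rises among the calls was 66.3%, and it was 54.9% after median-of-ratios rescaling, with 524 rises and 430 falls. Upper-quartile rescaling and totals without NFIC moved it the other way, to 73.5% (627 rises and 226 falls) and 70.2% (715 and 303). Without Control replicate 3 or NFIC1 replicate 1, 2 or 3, the number changed was 548, 441, 493 and 478. The low gene SLURP1 was listed at 0, 0.236 and 0.108 FPKM in Control and at 5.48, 5.80 and 5.48 in NFIC1. Some other named rises and falls are of genes whose reads could be split with another gene. PPAN-P2RY11 was listed at 0, 0.77 and 0 FPKM in Control and at 5.91, 3.63 and 3.31 in NFIC1, while SCHIP1 was listed at 1.71, 3.10 and 2.61 in Control and at 0.225, 0.143 and 0 in NFIC1. BEST1 overlaps FTH1, which lies on the other strand and was listed at 1607 to 1727 FPKM in Control and 1712 to 1815 in NFIC1. H2AC13 belongs to a family of near-identical histone genes, and its call was lost without NFIC1 replicate 1 or 2 (adjusted p = 0.0516 each) and with no filter (0.0738).

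Interferon genes were higher in NFIC1. Of 21 interferon genes listed, 4 reached the expression minimum and all 4 rose, which left too few for a list test. The type III interferons IFNL1, IFNL2 and IFNL3, which act mainly on epithelia, had log2 fold changes of 1.37 (SE 0.05), 1.62 (SE 0.12) and 1.48 (SE 0.06), and the type I interferon IFNB1 one of 1.51 (SE 0.11), with adjusted p between 2.58e-06 and 0.000112. In FPKM, IFNL1 went from 11.2 ± 0.434 to 30.5 ± 0.648 and IFNB1 from 2.29 ± 0.509 to 8.33 ± 0.855 (SD, n = 3 each). IFNL2 and IFNL3 are near-identical copies, so their separate values are uncertain.

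Interferon-stimulated genes rose as a group. Of 57 members tested, 37 were higher, 2 were lower and 18 did not pass. Adjusted over the list alone, 42 were higher and 2 lower. The members named are MX1, an antiviral GTPase (1.32, SE 0.05), IFI27 (1.99, SE 0.09), HERC6 (0.81, SE 0.04) and OAS2, which makes the second messenger of RNase L (0.76, SE 0.04). In FPKM, MX1 went from 24.9 ± 1.09 to 63.8 ± 3.61 and IFI27 from 123 ± 14.7 to 491 ± 36.2 (SD, n = 3 each). The list was called by camera (adjusted p = 6.73e-27) and also with an estimated correlation (adjusted p = 0.0103). The 2 that fell were TRIM21 (-0.25) and SP110 (-0.25), chosen for naming after their values were seen.

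**Figure D2:**
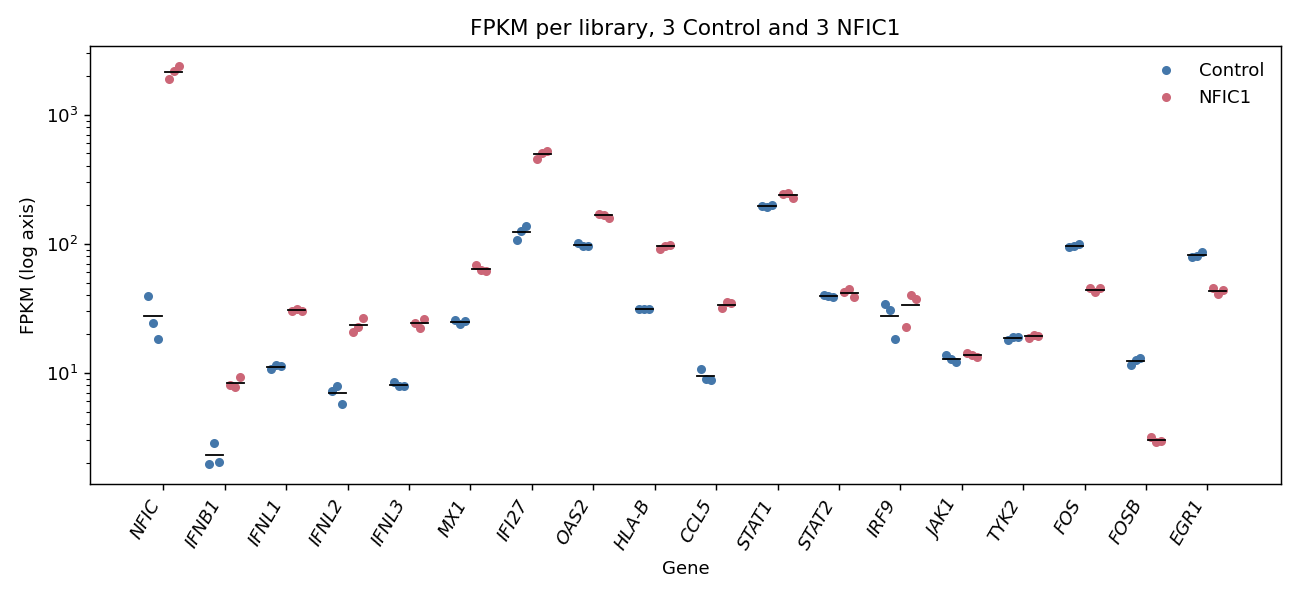
Points are FPKM per library on a log axis for Control (blue) and NFIC1 (red), and bars are the means of 3 libraries. IFNB1, IFNL1, MX1 and HLA-B lie apart between the groups, while STAT2 (39.3 and 41.8 FPKM), JAK1 (12.8 and 13.8) and TYK2 (18.6 and 19.2) have close means.

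The series title names the Jak-STAT pathway, whose kinases and STAT factors carry cytokine signals to the nucleus. Of 39 pathway components tested, 5 were higher, 0 were lower and 34 did not pass, with 8 higher and 1 lower adjusted over the list alone. STAT1, itself interferon-inducible, rose from 195 ± 3.09 to 239 ± 11.7 FPKM (SD, n = 3 each), a log2 fold change of 0.29 with SE 0.04 and a limma adjusted p of 0.00593. The feedback inhibitor SOCS2 (0.57), the interferon gamma receptor chain IFNGR1 (0.36) and the oncostatin M receptor OSMR (0.26) also rose, with adjusted p of 0.00989, 0.0172 and 0.0195. The call of IFNGR1 was lost without NFIC1 replicate 1, 2 or 3 (adjusted p = 0.0625, 0.0624 and 0.0579) and with no filter (0.0639), and that of OSMR without Control replicate 1 or 2 (adjusted p = 0.0554 and 0.0531) or NFIC1 replicate 1 or 2 (0.0675 and 0.0737). Changes in JAK1 (0.09, 95% interval -0.04 to 0.23), JAK2 (0.12, -0.12 to 0.36), TYK2 (0.05, -0.06 to 0.15), STAT2 (0.08, -0.04 to 0.21) and IRF9 (0.27, -0.31 to 0.84) did not pass, with adjusted p from 0.363 to 0.603. SOCS1, another feedback inhibitor, was not tested and was listed lower in NFIC1 (0.789 to 0.965 FPKM) than in Control (0.988 to 1.60 FPKM). The interferon lambda receptor chain IFNLR1 was not tested either, with means of 0.475 FPKM in Control and 0.418 in NFIC1. Neither reached 1 FPKM in 3 libraries, as the test asks, although SOCS1 had a mean of 1.38 FPKM in Control. Both were named after their values were seen. The list as a whole did not pass camera (adjusted p = 0.056, and adjusted p = 0.444 with an estimated correlation). It passed without Control replicate 1 (adjusted p = 0.0196) and without NFIC1 replicate 3 (adjusted p = 0.016), and under fry, which asks whether the members move one way on balance (adjusted p = 0.0381). Most lists passed under fry, which does not compare members with other genes.

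Antigen presentation genes were higher in 18 of 21 members tested, with 0 lower, and in 18 adjusted over the list alone. Most tested members act in the class I pathway, and HLA-DMA, of the class II pathway, did not pass (0.07, named after its value was seen). HLA-B rose from 31.1 ± 0.114 to 95.1 ± 3.98 FPKM (SD, n = 3 each; log2 fold change 1.58, SE 0.04). HLA-A (1.03, SE 0.05), HLA-C (1.01, SE 0.04) and B2M, the shared light chain (0.83, SE 0.04), rose as well, and all 4 adjusted p lay between 9.42e-07 and 4.12e-06. The HLA class I genes are close paralogs, so the split of reads among them is uncertain. The list passed camera (adjusted p = 1.01e-21) and kept its call with an estimated correlation (adjusted p = 0.0285). Genes of nucleic acid sensing, which include adaptors, kinases and transcription factors besides sensors, had 6 higher and 1 lower of 28 tested (7 and 2 adjusted over the list alone). SAMHD1, a dNTP hydrolase (0.90, SE 0.05), IFI16, a DNA sensor (0.80, SE 0.06), DHX58, a RIG-I-like receptor (0.69, SE 0.06), and TLR3, a receptor of double-stranded RNA (0.50, SE 0.08), rose with adjusted p from 1.85e-05 to 0.0103. That list did not pass camera (adjusted p = 0.0746, and adjusted p = 0.324 with an estimated correlation), but passed under fry (adjusted p = 0.00222) and with no filter on low values (adjusted p = 0.0066).

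NF-kB targets and chemokines were higher in 14 of 18 members tested, with 0 lower, and in 15 adjusted over the list alone. CCL5 went from 9.44 ± 1.01 to 33.7 ± 1.99 FPKM and the adhesion molecule ICAM1 from 5.21 ± 0.301 to 11.2 ± 0.0897 FPKM (SD, n = 3 each). The list passed camera (adjusted p = 4.55e-15) and kept its call with an estimated correlation (adjusted p = 0.0103).

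The title also names migration and invasion. Of 41 migration and invasion genes tested, 10 were higher and 1 was lower (14 and 1 adjusted over the list alone). The fibronectin receptor subunit ITGA5 (0.44, SE 0.05) and the urokinase receptor PLAUR (0.37, SE 0.05) rose, and RHOB fell by 0.69 on the log2 scale. The collagenase MMP13 rose (0.62, SE 0.09) near the expression minimum, from a mean of 0.932 to 1.96 FPKM. Of other MMP genes listed, MMP14 (0.28) and MMP15 (0.33) rose, and the rest, MMP2 and MMP9 among them, were below that minimum. The genes that rose also include the metalloproteinase inhibitor TIMP2 (0.19). MMP14, MMP15 and TIMP2 were named after their values were seen. Camera called the list higher (adjusted p = 0.03), and the call was lost with an estimated correlation (adjusted p = 0.321). It was also lost without Control replicate 2 (adjusted p = 0.13) and without NFIC1 replicate 1 (adjusted p = 0.0761). Mesenchymal genes had 2 higher of 22 tested, FN1 (0.50, SE 0.05) and LOX (0.24, SE 0.06), with 4 higher adjusted over the list alone. The list did not pass camera (adjusted p = 0.218) but passed under fry (adjusted p = 0.00305), as most lists did. Epithelial junction and keratin genes had 4 higher and 3 lower of 33 tested (5 and 4 adjusted over the list alone; camera adjusted p = 0.898), among them ST14 (0.32), CLDN7 (0.26), KRT7 (0.42) and KRT19 (-0.23). The call of LOX was lost without any 1 of the 6 libraries (adjusted p = 0.0745 to 0.114), that of KRT7 without NFIC1 replicate 2 or 3 (0.0554 and 0.0652) and that of KRT19 without Control replicate 3 or NFIC1 replicate 1 or 2 (0.0522, 0.0625 and 0.0673). With no filter the 3 had adjusted p of 0.07, 0.0677 and 0.0823. By limma, LOX also lost its call after median-of-ratios rescaling (adjusted p = 0.0591) and with the filter at 0.1 FPKM (0.0521), and KRT19 after upper-quartile rescaling (0.0558).

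**Figure D3:**
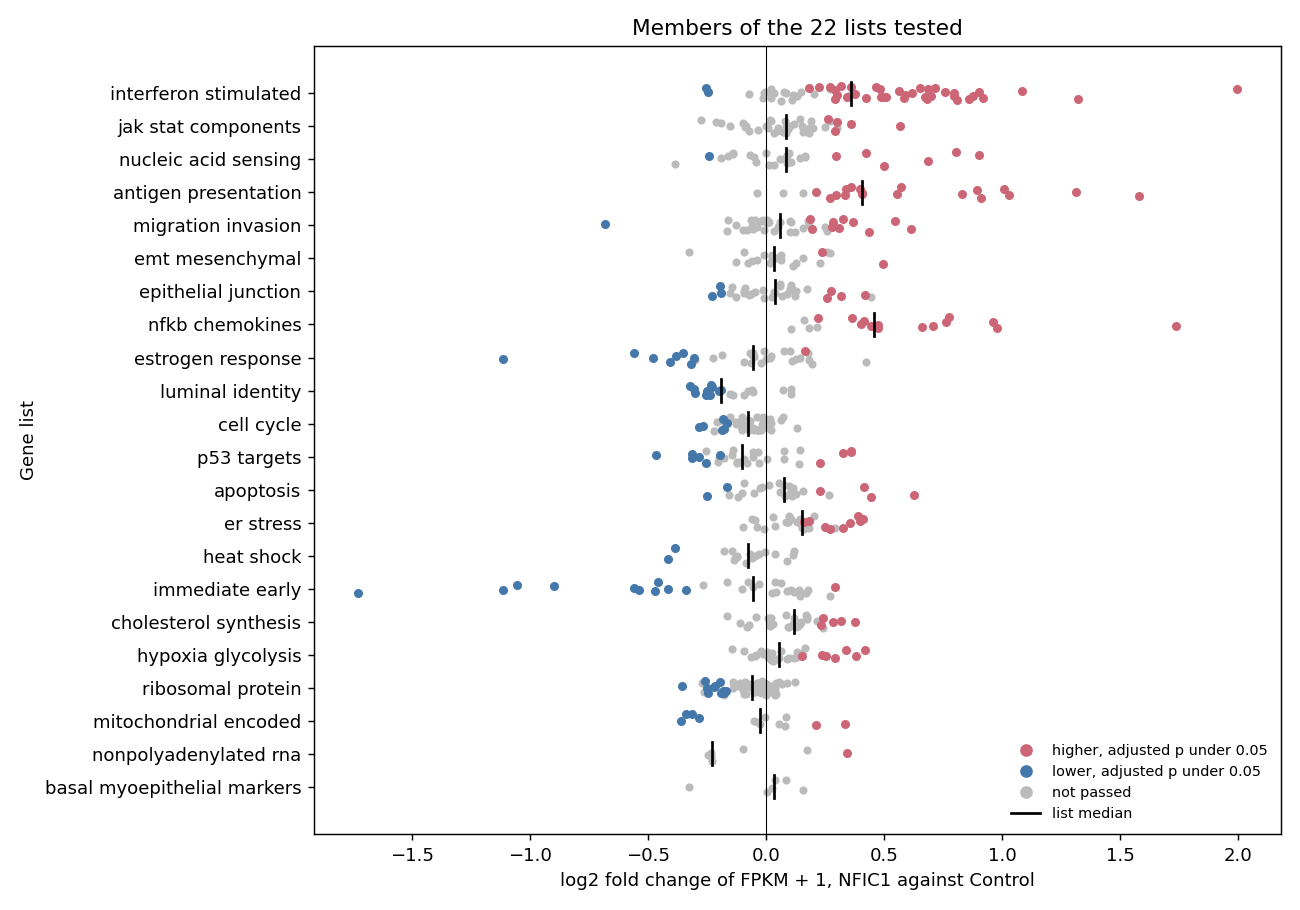
Each point is 1 tested member of a list, with its log2 fold change of FPKM + 1, NFIC1 against Control, on the x axis, red or blue where the adjusted p was under 0.05, and a black bar is the list median. Interferon-stimulated genes (37 of 57), antigen presentation (18 of 21) and NF-kB targets (14 of 18) have most members in red, and luminal genes (10 of 19) have most in blue.

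Genes that mark the luminal state of breast epithelium were lower in 10 of 19 members tested, with 0 higher (1 higher and 10 lower adjusted over the list alone). The transcription factors GATA3 (-0.32, SE 0.04, adjusted p = 0.0029) and FOXA1 (-0.24, SE 0.04, adjusted p = 0.00711) fell. The list passed camera (adjusted p = 2.02e-07) and kept its call with an estimated correlation (adjusted p = 0.0423). Estrogen-responsive genes had 8 lower and 1 higher of 33 tested (9 and 5 adjusted over the list alone), with FOS and cyclin D1, CCND1 (-0.35, SE 0.04), named by the rule. That call (camera adjusted p = 0.00179) was lost with an estimated correlation (adjusted p = 0.104), and the list median was -0.06. Some lists share members, so their results are not separate. FOS and EGR3 are also among the immediate-early genes called lower, and ESR1 is also among the luminal genes that fell.

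Immediate-early genes, which respond within minutes to growth factors and stress, had 10 lower and 1 higher of 29 tested (12 and 4 adjusted over the list alone). FOSB went from 12.3 ± 0.838 to 3.02 ± 0.157 FPKM and FOS from 96.7 ± 2.51 to 44.2 ± 1.85 FPKM (SD, n = 3 each). Camera called the list lower (adjusted p = 5.46e-05), and the call was lost with an estimated correlation (adjusted p = 0.104). The list median was -0.05 and the mean -0.23, and 16 of the 29 had a negative log2 fold change.

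Cell cycle genes had 6 lower and 0 higher of 50 tested, with 8 lower adjusted over the list alone, and TYMS (-0.28) and CDC20 (-0.19) are named. Their call (camera adjusted p = 6.36e-08) was lost with an estimated correlation (adjusted p = 0.0672). Ribosomal protein genes had 11 lower of 68, in both counts, with RPL7 (-0.25) and RPL6 (-0.26) named. Their call (camera adjusted p = 2.02e-07) was lost with an estimated correlation (adjusted p = 0.39) and under fry (adjusted p = 0.182). Targets of p53 went both ways, 4 higher and 6 lower of 30 (4 and 10 adjusted over the list alone), with PHLDA3 at -0.47 and PMAIP1 at 0.36, and the call of lower (camera adjusted p = 0.00179) was lost with an estimated correlation (adjusted p = 0.0672). Endoplasmic reticulum stress genes were higher in 9 of 30 (15 adjusted over the list alone), including PPP1R15A (0.36) and ASNS (0.39), and this call (camera adjusted p = 2.32e-06) was lost with an estimated correlation (adjusted p = 0.0892). Heat shock genes were lower in 2 of 18 (7 lower and 1 higher adjusted over the list alone), the near-identical pair HSPA1A (-0.39) and HSPA1B (-0.41), and the call (camera adjusted p = 0.000169) was lost with an estimated correlation (adjusted p = 0.0554). Cholesterol synthesis genes were higher in 5 of 32 (13 higher and 1 lower adjusted over the list alone), including MVD (0.24) and MSMO1 (0.38), and the call (camera adjusted p = 0.00124) was lost with an estimated correlation (adjusted p = 0.189). Hypoxia and glycolysis genes were higher in 7 of 31 (11 adjusted over the list alone), including P4HA1 (0.34) and SLC2A3 (0.42), and the call (camera adjusted p = 0.00755) was lost with an estimated correlation (adjusted p = 0.259). Apoptosis genes had 4 higher and 2 lower of 25 (5 and 2 adjusted over the list alone), with CASP4 (0.63) and TNFRSF10B (0.23) named, and the list did not pass camera (adjusted p = 0.365) but passed under fry (adjusted p = 0.0379). The call of CDC20 was lost without Control replicate 2 or 3 or any 1 NFIC1 library (adjusted p = 0.0538 to 0.115), that of RPL6 without NFIC1 replicate 1 (0.0585) and that of TNFRSF10B without NFIC1 replicate 2 or 3 (0.0608 and 0.052). With no filter CDC20 and RPL6 had adjusted p of 0.0716 and 0.0659. By limma, CDC20 also lost its call after upper-quartile rescaling (adjusted p = 0.0789) and with no mean-variance trend (0.0791).

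Other lists track RNA quality or other cells. Of 13 mitochondrially encoded genes, 2 were higher and 4 lower, in both counts, with MT-CO3 (-0.36) and MT-ATP8 (-0.34) named, and the list did not pass camera (adjusted p = 0.121), while fry found change in either direction (mixed adjusted p = 2.09e-05). The call of MT-ATP8 was lost without Control replicate 3 or NFIC1 replicate 1 (adjusted p = 0.0553 and 0.0618), and both named calls with no filter (0.149 for MT-ATP8 and 0.0753 for MT-CO3). Non-polyadenylated RNAs had 1 higher of 7 (2 adjusted over the list alone), the histone gene H2AC6 (0.34), while the list median was -0.23, and the list did not pass (camera adjusted p = 0.359). Basal and myoepithelial markers had 0 of 6 past the threshold by limma (camera adjusted p = 0.907), with a list median of 0.03 and a mean of -0.00284, which differ in sign. The other lists had too few tested members for camera. Among leukocyte markers, CD68, a lysosomal protein, rose from 30.9 ± 1.93 to 57.2 ± 0.97 FPKM (SD, n = 3 each), and 2 others were tested and did not pass, CORO1A (4.44 and 4.64 FPKM) and LAPTM5 (8.40 and 7.15 FPKM). The pan-leukocyte gene PTPRC was listed at a mean of 0.0134 FPKM in Control and 0.00424 in NFIC1. Among endothelial markers 1 of 3 tested rose, EGFL7 (0.38). Of fibroblast, embryonic kidney and nuclear RNA lists, 1, 2 and 1 members were tested, and 0 passed in each by limma. CD68, EGFL7 and H2AC6 were chosen for naming after their values were seen.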

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

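The robust prior, the fit with no trend, the fit on Ensembl genes only and the fold minimum of 0.5 were chosen after seeing the data. No named gene or list that passed the test reversed direction in any alternative run. Among those that did not pass, NFIX (0.01) turned to -0.0175 after median-of-ratios rescaling and was below 0 without Control replicate 2 or 3 or NFIC1 replicate 2 (range without 1 library -0.0578 to 0.0989), and NFIA (-0.03) turned to 0.0353 without Control replicate 1 (range -0.0620 to 0.0353). The epithelial junction list turned to lower after median-of-ratios rescaling (adjusted p = 0.99) and without Control replicate 2 or 3 or NFIC1 replicate 3 (range without 1 library 0.488 to 0.973), and the basal list with the replicate block (0.973) and without Control replicate 2 or 3 or NFIC1 replicate 1 or 2 (range 0.637 to 0.998). NFIC passed in every one. The main counts of 979 changed, 649 higher and 330 lower became 537, 392 and 145 with no filter on low values, where more rows are tested, 40, 35 and 5 with a fold minimum of 1, and 169, 142 and 27 with a fold minimum of 0.5. Median-of-ratios and upper-quartile rescaling gave 954 and 853 changed, of which 854 and 824 were shared with the main calls in the same direction. Leaving out 1 library gave 441 to 712 changed, 320 to 517 higher and 121 to 246 lower, with fewer samples, and the losses were over 1.5 times without Control replicate 3 (548) or NFIC1 replicate 1 (441), 2 (493) or 3 (478), and for the lower genes also without Control replicate 2 (195).

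With an estimated correlation 4 lists were called in place of 14, and migration and invasion went to an adjusted p of 0.321 and immediate-early genes to 0.104. Nucleic acid sensing passed with no filter (adjusted p = 0.0066), at 0.1 FPKM (0.00967) and under fry (0.00222). The Jak-STAT list passed under fry (adjusted p = 0.0381), as most lists did. Leaving out 1 library gave adjusted p of 0.016 to 0.22 for the Jak-STAT list, lowest without NFIC1 replicate 3 (0.016) and also past the threshold without Control replicate 1 (0.0196), and 0.00919 to 0.13 for migration and invasion, lost without Control replicate 2 (0.13) and NFIC1 replicate 1 (0.0761). The cause was not tested.

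Of 73 named genes, 11 lost their call in 1 alternative or more other than a fold minimum (CDC20, H2AC13, IFNGR1, KRT19, KRT7, LOX, MT-ATP8, MT-CO3, OSMR, RPL6 and TNFRSF10B). Over named genes and those alternatives, 48 of 1168 results no longer passed, 5 changed sign as given, and 1115 stayed on their side. Replicate numbers gave no sign of pairing, since deviations of libraries with the same number correlated at 0.0605, -0.108 and -0.0657. Pairing without a strong shared effect would not be seen this way. With the replicate block 584 were changed, 414 higher and 170 lower. DESeq2, limma-voom, TMM factors and filters on counts were not run, because they need counts. Unknown depth leaves the precision of low genes unstated.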

Other observations

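The tests of nucleic acid sensing, white blood cells, a group-wide difference in handling, overlapping genes and Control level were chosen after the results were seen, as were the genes in the next 2 paragraphs.

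Some complement genes besides CFB were higher in NFIC1. They were picked after the values were seen and were not tested as a group, so their tally (8 of 9 tested higher and 0 lower by limma, of 14 picked) describes the choice as much as the cells. C1R, a protease of the classical pathway, went from 1.27 ± 0.0763 to 5.49 ± 0.369 FPKM (SD, n = 3 each; log2 fold change 1.51, SE 0.07), and the inhibitors SERPING1 (0.75, SE 0.15), CFH (0.61, SE 0.12) and CD55 (0.43, SE 0.05) rose as well. CD46 (0.23), C4A (0.49) and C4B (0.61) rose too, the last pair being near-identical copies. CD59 did not pass (0.24, adjusted p = 0.149 by limma), C5 had means of 0.757 and 0.739 FPKM, and C2 was listed lower in NFIC1 (0.254 to 0.336 FPKM) than in Control (0.596 to 0.850 FPKM). C1S (means of 0.330 and 1.09 FPKM) and C3 (0.265 and 0.633 FPKM) were listed higher in NFIC1. C1S, C2, C3 and C5 did not reach 1 FPKM in 3 libraries, so they were not tested. Of 33 Ensembl genes that rose by 1 or more on the log2 scale, 20 are in none of the lists. They include UBA7, the enzyme that activates ISG15 (1.20, SE 0.06), PLAAT4 (1.65, SE 0.09), LGALS9 (1.61, SE 0.07), the stress-induced NUPR1 (1.72, SE 0.20), MUCL1, a small mucin (1.14, SE 0.04), the gap junction gene GJB2 (1.09, SE 0.10) and SERPINA3, an acute-phase inhibitor (1.05, SE 0.10).

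Interferon-stimulated genes were already abundant in Control. They made up 1.56% ± 0.00781 of the FPKM sum there and 2.28% ± 0.0324 in NFIC1 (SD, n = 3 each). ISG15 stood at 924 ± 83.6 FPKM and IFI6 at 568 ± 54.9 FPKM in Control. The rise was uneven, since USP18 (62.0 and 61.9 FPKM), CMPK2 (28.8 and 29.2), EIF2AK2 (45.6 and 46.3) and IRF7 (87.1 and 89.2) had close means in the groups. One hypothesis was that genes already high in Control rise less. Across the 57 genes, which are not independent replicates, the level in Control replicate 1 and the fold over Control replicates 2 and 3 had a Spearman rho of -0.09 (permutation p = 0.506, bootstrap 95% interval -0.318 to 0.166) and a Pearson r of -0.059 (permutation p = 0.663; -0.0777 without the 2 genes farthest from the median). This does not meet what the hypothesis asked for, and a weak relation within that interval stays open. The log2(FPKM + 1) scale understates the change of low genes, which works against the hypothesis. The low members CXCL10 and GBP2 were not tested and are not among the 57. No other relation was computed.

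The rise of interferon-stimulated genes was weighed against 4 technical explanations. Scaling between libraries is argued against by 97.3% of the members called higher staying so after median-of-ratios rescaling. At least 86.5% stayed so without any 1 of the 6, but they were called on the same libraries, so this partly restates the choice. The whole list, whatever its calls, made up 1.56% to 1.57% of the FPKM sum in the Control libraries and 2.25% to 2.30% in the NFIC1 libraries. That argues against a single library for the list as a whole. White blood cells are argued against because 15 leukocyte markers other than CD68 changed together by -0.145% of the summed rise of HLA-B, HLA-C and B2M, with the most abundant, LAPTM5, at 8.40 FPKM in Control and 7.15 in NFIC1. Stronger sensing of transfected nucleic acid in the NFIC1 dishes cannot be told apart from an effect of the NFIC1 protein, because IFNB1 was at 1.97 FPKM or more in each Control library and no untransfected cells or other insert were compared. An effect of NFIC1 on interferon genes may therefore be a candidate explanation, and the amount of vector taken up another.

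The fall of immediate-early genes was weighed against handling. For 10 of the 10 members called lower the difference between group means was above the larger range within a group. These members were called on their difference relative to that same spread, so the count restates the choice, and handling that differed from dish to dish stays open, although the bound set before the result was seen was met. A difference in handling or harvest between the groups of dishes cannot be told apart from an effect of NFIC1. Either would separate the same libraries, and the labels give no harvest order. Of the 29 members tested, 55.2% had a negative log2 fold change, between the shares set for either reading. No share could have decided the question for that reason, and no conclusion is drawn from it.

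For 3 of the named genes, reads assigned to an overlapping gene were weighed, with FPKM summed over the gene and its partners, which is approximate because lengths differ. SCHIP1 shares 21.5% of its exonic bases in GENCODE 29 with IQCJ-SCHIP1, which went from 5.35 ± 0.281 to 8.30 ± 0.557 FPKM (SD, n = 3 each), and the sum differed by 0.597 FPKM, less than the larger range within a group of 1.21, so the fall may come from how reads were assigned or from a shift between transcripts. PPAN-P2RY11 rose by 4.03 FPKM, while its partners PPAN and P2RY11 together changed by -1.24 FPKM. The sum of the 3 rose by 2.78 FPKM, against a larger range of those partners of 2.08. PPAN-P2RY11 shares 54.4% of its exonic bases with PPAN and 43.1% with P2RY11, so reads in most of its exons could belong to a partner. PPAN alone was listed at 34.1 to 36.5 FPKM in Control. The rise was thus larger than the fall of the partners, but how reads were assigned stays open. For BEST1 the sum with FTH1 rose by 98.1 FPKM, within the larger range of FTH1 of 120. The rise of BEST1 alone, 12.3 FPKM, was below that range, so the sum could not decide the question. FTH1 had means of 1664 FPKM in Control and 1750 in NFIC1 (limma adjusted p = 0.376). BEST1 had means of 1.02 and 13.3 FPKM, with no overlap between groups. A steady share of FTH1 reads would have risen only as FTH1 did, so these values argue against a steady share. A share that differed between the groups stays open.

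The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 979 changed genes and the highest other split 2, and 1 of the 10 splits, the real one, gave as many. The real split called 14 lists with the preset correlation and the highest other 11, and 1 of the 10 gave as many. With an estimated correlation the real split called 4 lists and the other splits 0, by camera. Each other split mixes the groups, so the group difference enters its spread and can lower its calls. The numbers from those splits are therefore no background for calls by chance.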
